A study of Mus musculus with 123 samples.

How the data were processed

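RNA was measured in SCN samples of male mice with stranded, poly-A-selected, paired-end libraries, per the labels' protocols. The submitters' processing notes name Trim Galore 0.6.7, cutadapt 1.18, STAR 2.7.9a and HTSeq, and the builds mm39 and GRCm39. The version and strand setting of HTSeq are not given in the sources used here, so antisense and overlapping genes are uncertain. The values used are raw read counts per gene as deposited by the authors, in 123 files of 56980 Ensembl identifiers each. Each file held whole numbers, with totals that differed between files.

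No file could be matched to a sample, because no label used here names a file. Whether the library numbers follow the order of the labelled samples was not tested, and that order was not used for a match. Each file was placed in a sequencing batch from the batch number that its name and the labels share, and this was used only as a technical batch. The labels also name RNA extraction batches within each sequencing batch, which hold different times. They could not be matched to files and are a term in no fit, and the permutations and random splits treat the libraries as exchangeable, within a sequencing batch or, for the comparisons of 5209 with 5728, across both. The tests of LONG against SHORT, of rhythms, of phases and of gene lists between photoperiods that were chosen before the data were examined need that match and were not run. The 3 results chosen beforehand for that case were computed in their place. They are correlations of clock genes with Arntl, genes varying with 2 clock gene axes, and differences between batches. Gene symbols came from GENCODE M21, an annotation of the build GRCm38, matched without the version suffix, and named 91.4% of identifiers and 99.2% of counts. No coordinates are given, because the counts were made on another build. Mitochondrially encoded, ribosomal protein, haemoglobin and HSP70 genes share reads with near-identical copies and are uncertain.

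Counts were scaled with TMM in edgeR 4.0.16 (R 4.3.3) and filtered with its default rule by batch, which kept 19412 genes. Log2 CPM used a prior count of 2. Correlations used 100000 two-sided permutations within batches and Benjamini-Hochberg adjustment, and the spread of Arntl, Tshb and both axes into components was checked with mclust 6.1.1. Axis 1 was the mean z score of Nr1d1, Dbp and Ciart minus the z score of Arntl, and axis 2 the mean z score of Per2 and Cry1, each rescaled to an SD of 1. Genes varying with the axes were tested with edgeR's quasi-likelihood F test on both axes, with batch as a term and without the 6 axis genes. Each axis was also tested alone, for the direction of a gene. Adjusted p under 0.05 was the threshold. Lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and with an estimated one, over 64 tests. A call adjusted over the list alone uses only the members of that list. A test of whether slopes differ between batches 5209 and 5728 was added after the data were seen. The genes named on the axes are the 10 with the smallest p at 1 CPM or more and members of 29 lists, a rule set before the data were examined. Bc1, and genes of 3 further lists for pituitary, olfactory epithelium and nuclear-retained noncoding RNA, were chosen after values were seen. Some list members are not reported here by name. They count in the lists but not among the single genes recomputed under each alternative.

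No pair of libraries within a batch agreed within sampling noise: the smallest chi-square per degree of freedom, over genes with at least 20 counts in the pair, was 4.58. Ddx3y, a Y-linked gene, was at 45.2 CPM or more in each library, and Xist at 0.462 CPM or less. The 3 libraries called apart had a TMM factor under 0.9 or a median correlation under 0.97 with the others, limits set after the data were seen. They are library 38 of batch 5209 (TMM factor 0.453), library 16 of 5209 (0.780) and library 95 of 5728 (0.852). The tests were tried on simulated counts for 19412 genes, of which 200 were changed. The axis test recovered 70.0% of changes of 0.1 and 97.0% of changes of 0.25 log2 per SD. The batch test recovered 75.0% of changes of 0.25 and 96.0% of changes of 0.5, and the test of slope differences 23.0% of changes of 0.1 and 69.0% of changes of 0.25. Unchanged genes made up 3.47%, 4.47% and 4.17% of the calls. The simulated counts were drawn independently for each gene and library, without blocks that share time, photoperiod or RNA extraction batch. These rates therefore do not cover errors from such blocks. Alternatives were RLE scaling, no filter, limma-voom, DESeq2 1.42.0, each batch left out, no batch term, axis 1 alone, Spearman's rho, a prior count of 0.5, covariates for tissue content, neighbouring tissue, glial content and library quality, and libraries left out. Total counts per library ran from 10698007 to 76951256, and depth limits the precision of genes near 1 CPM.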

Results

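Messenger RNA was measured by sequencing in the suprachiasmatic nucleus (SCN), the hypothalamic nucleus that holds the central circadian clock of mammals, dissected from male mice of a strain with intact melatonin signalling, per the labels. The mice were raised from embryonic day 0 under a LONG day of 16 h light and 8 h dark or a SHORT day of 8 h light and 16 h dark, and were placed in constant darkness at 50 days of age. Tissue was collected from 36 to 80 h after lights off, every 4 h, to compare SCN transcript rhythms between photoperiods. The labels list 123 samples, with 8 to 16 per photoperiod at each of 6 projected zeitgeber times, in 3 sequencing batches. Batch 3518 holds 16 SHORT samples, batch 5209 holds 35 LONG and 16 SHORT samples, and batch 5728 holds 30 LONG and 26 SHORT samples. The 123 count files were placed in these batches but could not be matched to an animal or a time, nor, in 5209 and 5728, to a photoperiod. LONG against SHORT, rhythms and phases were therefore not analysed here. The results describe how transcripts varied together from library to library, and their p-values measure spread over libraries mixed in photoperiod and time. Total counts per library ran from 10698007 to 76951256, with a median of 46780511. Batch medians were 45263252 in 3518, 30440063 in 5209 and 55040482 in 5728.

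The first comparison asked how clock genes varied with Arntl (ENSMUSG00000055116.9), which encodes the clock activator BMAL1. Several targets and repressors of BMAL1 were low where Arntl was high. With each batch centred, Dbp, a PAR bZIP transcription factor gene driven by BMAL1, had Pearson's r = -0.812 and Spearman's rho = -0.791 (n = 123). Ciart, a repressor gene, had r = -0.771 (rho = -0.760), and Nr1d2, a nuclear receptor gene whose product represses Arntl, had r = -0.726 (rho = -0.757). The period genes Per2 (r = -0.698, rho = -0.736) and Per1 (r = -0.670, rho = -0.706) were also negative, as were Bhlhe41 (r = -0.573, rho = -0.589) and Tef (r = -0.553, rho = -0.543). Npas2, which encodes a partner of BMAL1, rose with Arntl (r = 0.643, rho = 0.657), and so did Nfil3, a repressor of PAR bZIP targets (r = 0.615, rho = 0.588). For these 9 genes the permutation p was 1e-05 for both coefficients, the smallest that 100000 two-sided permutations within batches can give. Benjamini-Hochberg adjusted p over 64 relations was 3.05e-05 for r and 2.78e-05 for rho. Smaller coefficients passed for Nr1d1 (r = -0.317, adjusted p = 0.00113), Per3 (r = -0.256, adjusted p = 0.00848) and the neuropeptide gene Avp (r = -0.235, adjusted p = 0.0162). Avp did not pass by rho (adjusted p = 0.0647). Cry1 (r = -0.168), Prok2 (r = -0.0938), Vip (r = 0.0133) and Rgs16 (r = -0.0803) did not pass, so that 12 of 16 genes passed, 10 with a negative and 2 with a positive r. Without the 2 libraries farthest from the Arntl median, r was -0.800 for Dbp, -0.761 for Ciart, -0.790 for Nr1d2, -0.759 for Per2 and 0.664 for Npas2.

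**Figure D1:**
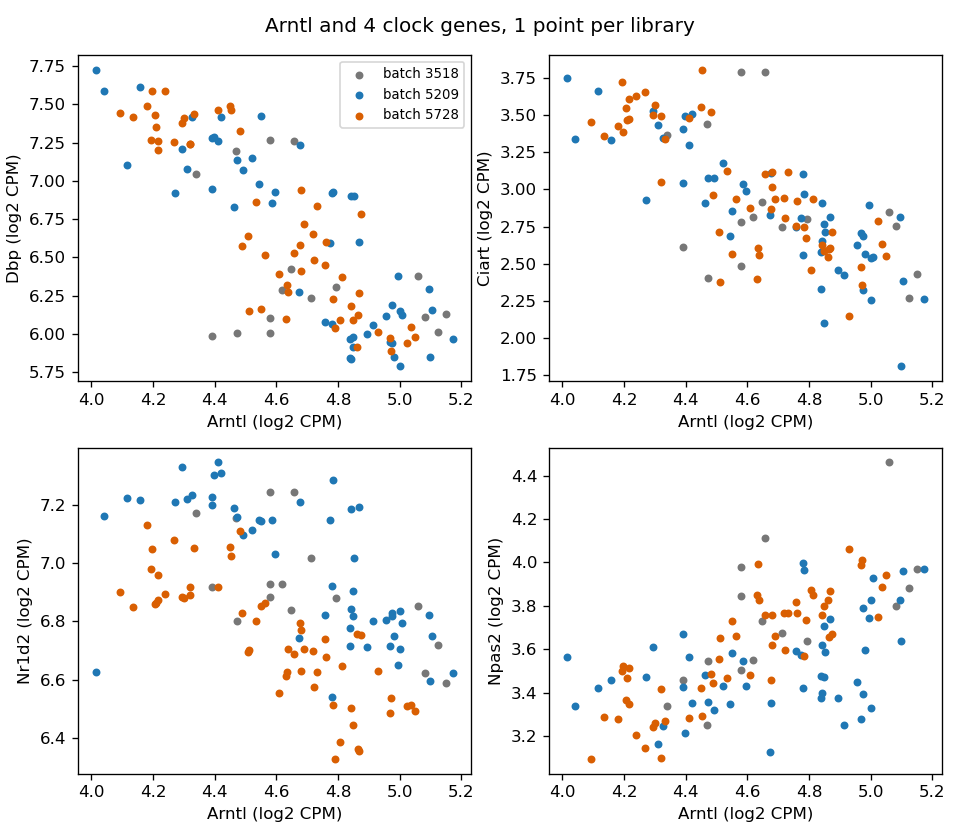
Each point is 1 of the 123 libraries, coloured by sequencing batch, with Arntl on the x axis and Dbp, Ciart, Nr1d2 or Npas2 on the y axis, all in log2 CPM. Dbp, Ciart and Nr1d2 are lower where Arntl is higher (r = -0.812, -0.771 and -0.726 with each batch centred), and Npas2 is higher (r = 0.643).

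Within batch 5728 (n = 56) r was -0.878 for Dbp, -0.815 for Ciart, -0.807 for Nr1d2 and 0.840 for Npas2, and 12 of the 16 genes passed. Within batch 5209 (n = 51) these values were -0.851, -0.843, -0.669 and 0.437, and 11 genes passed. Per3 (r = 0.0947) and Avp (r = 0.0115) did not pass in 5209, where Prok2 did (r = -0.319). Within batch 3518 (n = 16) 6 genes passed, among them Per3 (r = -0.874), Per2 (r = -0.859), Nr1d2 (r = -0.676) and Npas2 (r = 0.662). Dbp (r = -0.349), Ciart (r = -0.395), Nr1d1 (r = 0.197) and Bhlhe41 (r = 0.127) did not pass there. Arntl levels were not evenly spread. A mixture of 2 normal components had a higher Bayesian information criterion than 1, by 3.49 in 3518, 2.22 in 5209 and 1.27 in 5728. The largest gap between neighbouring libraries was 0.0981 of the range in 5209 and 0.0835 in 5728, but 0.328 in 3518, where 4 libraries stood above the other 12. Within those 12 no gene passed: Per2 had r = -0.549 (permutation p = 0.0651) and Npas2 had r = 0.553 (permutation p = 0.0634). The other 4 genes that passed in 3518 had r of -0.470 for Per3, -0.263 for Per1, -0.173 for Nr1d2 and 0.0598 for Nfil3 among the 12, against -0.874, -0.618, -0.676 and 0.593 in the 16. The calls in 3518 thus needed the 4 libraries, and whether the relations hold among the 12 was not settled. By the labels 3518 holds samples at projected zeitgeber times 0, 4, 8 and 16 and none at 12 or 20. Batches 5209 and 5728 hold samples at each time, so values of 3518 are not directly comparable with theirs. A component spans a narrower range of Arntl and holds fewer libraries than its batch, which by itself can weaken r. Over the 5 components of at least 6 libraries (80 relations), by r, Dbp kept its sign in 5 and passed in 4, and Ciart kept it in 5 and passed in 3. Per2 and Nr1d2 passed in 2, and kept their sign in 3 and 4. Tef passed in 2, Per1, Npas2 and Nfil3 in 1, and Bhlhe41 in 0. By rho Dbp kept its sign in 4 and passed in 1, and Ciart kept it in 4 and passed in 2, with rho of 0.182 and 0.0909 in the 12 libraries of 3518. Tef passed in 2 by rho, and Per1, Per2, Nr1d2, Npas2 and Nfil3 in 1. By r Nr1d1 kept its sign in 1 of the 5, where it passed. In the lower component of 5209 it passed with the opposite sign (r = 0.652, rho = 0.704, adjusted p = 0.0149), as did Cry1 in the lower component of 5728 (r = 0.513, rho = 0.359, adjusted p = 0.0477 for r and 0.227 for rho).

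The second comparison asked which other genes varied with the clock genes. Each library was placed on 2 axes. Axis 1 was the mean standardised level of Nr1d1, Dbp and Ciart minus that of Arntl, and axis 2 was the mean standardised level of Per2 and Cry1. Slopes are in log2 per SD of an axis at a fixed value of the other axis. Core clock genes outside the 6 that define the axes varied with them for 17 of 18 measured members, and for 17 when adjusted over the list alone. On axis 1 9 were higher and 6 lower, and on axis 2 11 were higher and 1 lower. Per1 had slopes of 0.19 (SE 0.019) on axis 1 and 0.16 (SE 0.020) on axis 2, and Nr1d2 had 0.13 (SE 0.012) and 0.10 (SE 0.013). Nfil3 had -0.25 (SE 0.021) on axis 1, Npas2 had -0.14 (SE 0.023), and Clock, which encodes the usual partner of BMAL1, had -0.14 (SE 0.016). Rorb did not pass (adjusted p = 0.318), and without batch 5728 neither did Npas2 (Npas2 axis 1 slope -0.082, adjusted p = 0.0719). With marker levels of glial cells as covariates the Clock axis 1 slope was -0.080. The list was higher than other genes on axis 2 by camera with a preset correlation (adjusted p = 3.02e-04) but not with an estimated one (adjusted p = 0.108 with an estimated correlation).

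Over all 19406 genes outside the 6, 10719 (55.2%) varied with the axes at an adjusted p under 0.05 in edgeR's quasi-likelihood F test of both axes, with batch as a term. On axis 1, 4131 genes were higher and 4335 lower, and on axis 2, 3363 were higher and 3253 lower. Of the genes that passed, 4673 had a slope over 0.1 on either axis, and 811 a slope over 0.25. The counts of list members that passed are to be read against the 55.2% of all genes. The axes correlated at r = 0.497, and at 0.0731, 0.50 and 0.632 within 3518, 5209 and 5728. Without the 3 libraries that stood apart, the count was 10379. The axes are transcript levels, so dissection, RNA quality, RNA extraction batch, photoperiod and time of day can each enter a slope.

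The 10 genes with the smallest p at 1 CPM or more were Nr1d2, Rbm3, Cirbp, Lman2l, Per1, Tardbp, Klf9, Dtx4, Tubgcp4 and Npbwr1. Cirbp (ENSMUSG00000045193.14) and Rbm3 (ENSMUSG00000031167.17), which encode RNA-binding proteins induced by mild cold, rose with axis 1 by 0.42 (SE 0.024) and 0.40 (SE 0.032), at medians of 87.8 and 43.1 CPM. Their adjusted p in edgeR was 9.20e-34 and 6.99e-34. Tardbp, the gene of the RNA-binding protein TDP-43, changed with axis 1 by -0.23 (SE 0.014), and Tubgcp4, which encodes a part of the gamma-tubulin ring complex, by -0.19 (SE 0.011). Lman2l had -0.17 (SE 0.013) on axis 1 and Dtx4 had -0.12 (SE 0.011). Klf9, a transcription factor gene induced by glucocorticoids, rose with axis 2 by 0.21 (SE 0.019) and with axis 1 by 0.11 (SE 0.017). Npbwr1, which encodes a receptor of neuropeptides B and W, rose with axis 2 by 0.32 (SE 0.018) and changed with axis 1 by -0.18 (SE 0.017).

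The heat shock genes were lower where axis 1 was higher. Of the heat shock and cold inducible list 18 of 18 measured members passed, and 18 when adjusted over the list alone, with 16 lower and 2 higher on axis 1. The 2 that rose were Cirbp and Rbm3, and the 16 that fell were genes of chaperones, their partners and the heat shock factor Hsf1. Hspa1b (ENSMUSG00000090877.4), an inducible HSP70 gene, had a slope of -1.09 (SE 0.12) on axis 1 and 1.07 (SE 0.11) on axis 2. Each slope holds at a fixed value of the other, correlated axis. In a fit with axis 1 alone the 16 heat shock slopes were all negative, and the lowest was -0.645. Hspb1 had -0.52 (SE 0.048) on axis 1, Chordc1 had -0.36 (SE 0.028) and Hsph1 had -0.32 (SE 0.022). The abundant chaperone genes Hspa8 and Hsp90aa1, at 1063 and 1212 CPM, had -0.16 (SE 0.018) and -0.15 (SE 0.014). On axis 2, 10 members were higher, including Rbm3 at 0.23 (SE 0.035), and 1 was lower, Cirbp at -0.087 (SE 0.026). The list was lower than other genes on axis 1 by camera with a preset correlation of 0.01 (adjusted p = 3.73e-12) and did not pass with an estimated correlation (adjusted p = 0.174 with an estimated correlation). On axis 2 the values were 2.19e-05 and 0.940. Hspa1a and Hspa1b are near-identical copies, so the split of reads between them is uncertain.

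**Figure D2:**
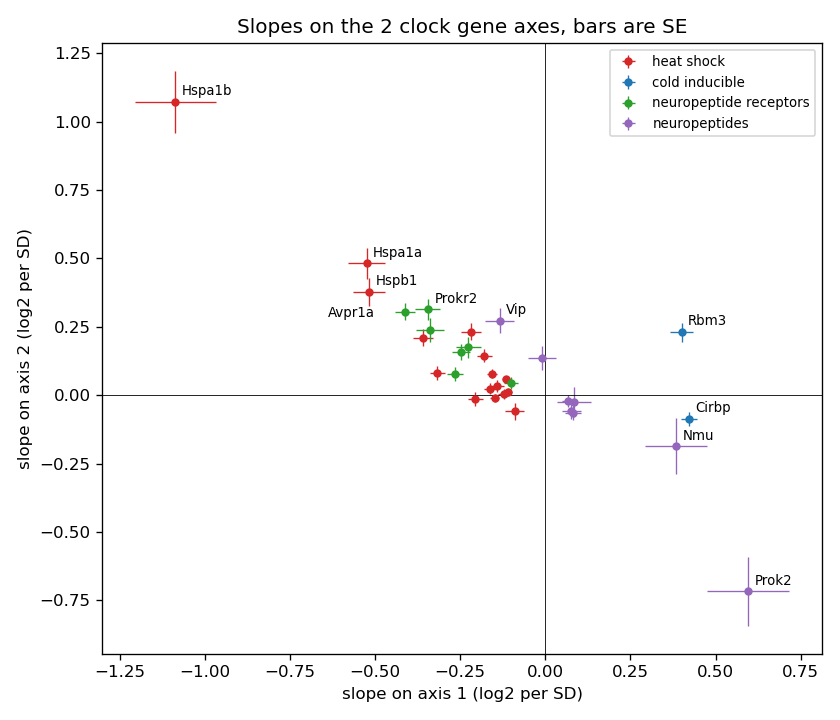
Each point is a gene, with its slope on axis 1 on the x axis and on axis 2 on the y axis, both in log2 per SD. Each slope is at a fixed value of the other axis, bars are standard errors and colours are gene groups. Hspa1b lies at -1.09 and 1.07, Cirbp at 0.42 and -0.087, Prok2 at 0.60 and -0.72, and Avpr1a at -0.41 and 0.31.

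Several neuropeptide receptor genes fell with axis 1 and rose with axis 2. Of the neuropeptide and receptor list 17 of 24 measured members passed, and 17 when adjusted over the list alone. On axis 1 6 were higher and 8 lower, and on axis 2 9 were higher and 3 lower. Avpr1a, a vasopressin receptor gene, had -0.41 (SE 0.029) on axis 1 and 0.31 (SE 0.032) on axis 2. Prokr2, the receptor gene for prokineticin 2, had -0.35 (SE 0.037) and 0.31 (SE 0.038), and Vipr2, a receptor gene for vasoactive intestinal peptide, had -0.34 (SE 0.041) and 0.24 (SE 0.044). Grpr, Nmur2 and Npy1r also fell with axis 1, with slopes of -0.23, -0.25 and -0.26, and had 0.18, 0.16 and 0.079 on axis 2. Prok2, which encodes a secreted output signal of the SCN, went the other way, with 0.60 (SE 0.12) and -0.72 (SE 0.13) at a median of 1.58 CPM. Penk rose with axis 1 by 0.068 (SE 0.019), Tac1 by 0.082 (SE 0.024) and Pcsk1n by 0.089 (SE 0.018). Vip had -0.13 (SE 0.042) and 0.27 (SE 0.045). Avp, at a median of 681 CPM, did not pass (axis 1 slope 0.084 (SE 0.050), adjusted p = 0.281). Without batch 5209 the Penk axis 1 slope was 0.0071 (adjusted p = 0.450 for both axes), the Tac1 axis 1 slope 0.074 (adjusted p = 0.107 for both axes) and the Pcsk1n axis 1 slope 0.057 (adjusted p = 0.0725 for both axes). With the mean levels of astrocyte, oligodendrocyte precursor and microglial markers as covariates, called glial covariates from here and chosen after values were seen, the Penk axis 1 slope was 0.029 (adjusted p = 0.0863 for both axes) and the Tac1 axis 1 slope 0.051 (adjusted p = 0.210 for both axes). The Pcsk1n axis 1 slope was 0.039 and the Grpr axis 1 slope -0.14, and both passed.

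Of the regional SCN transcription factor and marker genes 15 of 23 passed, and 15 when adjusted over the list alone. On axis 1 4 were higher and 9 lower. Lhx1, a homeobox gene needed for coupling of SCN neurons, had -0.28 (SE 0.033) on axis 1 and 0.22 (SE 0.035) on axis 2, and Gpr176, an orphan receptor gene of the SCN, had -0.14 (SE 0.012) and 0.11 (SE 0.013). Rgs16, a regulator of G protein signalling, rose with axis 1 by 0.31 (SE 0.058) and changed with axis 2 by -0.25 (SE 0.062). The SCN neuron marker list, whose 12 genes all stand in other lists as well, passed for 10 of 12 and for 10 when adjusted over the list alone, with 2 higher and 7 lower on axis 1. It was higher than other genes on axis 2 by camera with the preset correlation (adjusted p = 0.0118) but not with an estimated one (adjusted p = 0.940 with an estimated correlation). The mean level of this list did not correlate with axis 1 (r = -0.0112, rho = -0.0243, permutation p = 0.904) or axis 2 (r = 0.0974, rho = 0.00413, permutation p = 0.30) at the threshold, with each batch centred.

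Of the cAMP and MAPK genes 15 of 24 passed, and 15 when adjusted over the list alone, and on axis 2 10 were higher and 4 lower. Rasd1, a small G protein gene with a part in light input, had -0.25 (SE 0.034) on axis 1 and 0.51 (SE 0.035) on axis 2, whereas Rasl11b had 0.49 (SE 0.080) and -0.51 (SE 0.085) and the phosphatase gene Dusp4 had 0.29 (SE 0.065) and -0.28 (SE 0.068). Creb1 and Crem, of the cAMP response element family, fell with axis 1, with slopes of -0.16 (SE 0.016) and -0.17 (SE 0.016). The list passed camera on axis 2 with the preset correlation (adjusted p = 0.0181) but not with an estimated one (adjusted p = 0.940 with an estimated correlation). Immediate early genes, which respond to acute stimulation, passed for 8 of 22, or 6 when adjusted over the list alone. Klf4 had 0.20 (SE 0.030) on axis 2 and Fosl2 had -0.20 (SE 0.037) on axis 1, while Fos (adjusted p = 0.532) and Egr1 (adjusted p = 0.666) did not pass. GABA and chloride transport genes passed for 9 of 24, and 9 when adjusted over the list alone. On axis 2 7 were higher and 0 lower, with the kinase genes Wnk2 at 0.12 (SE 0.023) and Wnk1 at 0.10 (SE 0.028). Gad1, which encodes a GABA-synthesising enzyme, did not pass (adjusted p = 0.198). The immediate early and GABA lists passed for a smaller share than the 55.2% of all genes. The median axis 2 slopes of the cAMP and MAPK, immediate early and GABA lists turned with glial covariates. They went from 0.031 to -0.0088, from 0.046 to -0.016 and from 0.034 to -0.019. With glial covariates the Klf4 axis 2 slope was 0.075 (adjusted p = 0.0757 for both axes), the Wnk2 axis 2 slope 0.021 (adjusted p = 0.0312 for both axes) and the Wnk1 axis 2 slope -0.057 (adjusted p = 0.0314 for both axes), so that Wnk1 turned.

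Ion channel genes passed for 14 of 28 and 14 when adjusted over the list alone. The ion channel, dopamine and serotonin, glutamate receptor, matrix, DNA methylation and melatonin lists each passed for a smaller share than the 55.2% of all genes. Kcna1, a potassium channel gene, had -0.13 (SE 0.033) on axis 1 and 0.17 (SE 0.035) on axis 2, Kcnn2 had 0.17 (SE 0.020) on axis 2 and Hcn3 had -0.12 (SE 0.015). Dopamine and serotonin genes passed for 8 of 16 and 8 over the list alone, led by Htr1b, a serotonin receptor gene, at -0.20 (SE 0.025) on axis 1 and Drd1, a dopamine receptor gene, at 0.15 (SE 0.028) on axis 2. Glutamate receptor genes passed for 8 of 17 and 8 over the list alone, with -0.092 (SE 0.021) on axis 1 for Gria3. Matrix and adhesion genes passed for 10 of 22, or 9 when adjusted over the list alone, with Vcan at 0.17 (SE 0.025) and Hapln1 at 0.17 (SE 0.024) on axis 2. DNA methylation genes passed for 5 of 14, or 4 when adjusted over the list alone. Dnmt3a, a DNA methyltransferase gene, did not pass (adjusted p = 0.0542). Of the melatonin and thyroid hormone list 3 of 15 passed, and 3 when adjusted over the list alone. These were the melatonin receptor gene Mtnr1a, at -0.25 (SE 0.075) on axis 1 and 1.05 CPM, Thra at 0.059 (SE 0.012), and Slco1c1, which passed on both axes jointly (adjusted p = 0.00323). With glial covariates the Kcna1 axis 2 slope was -0.016 (adjusted p = 0.883 for both axes) and the Vcan axis 2 slope 0.023. Vcan is one of the genes averaged in those covariates, so its slope there is not independent of them. The Drd1 axis 2 slope was 0.086 and the Thra axis 1 slope 0.023 with them, and 19 matrix and 3 DNA methylation genes passed. Thra did not pass without batch 5209, where the Thra axis 1 slope was 0.032 (adjusted p = 0.224 for both axes). For dopamine and serotonin, SCN neuropeptide, glutamate receptor, melatonin, ependymal, choroid plexus and erythrocyte lists the median slope, the mean slope and camera differed in sign on an axis.

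Ribosomal protein and oxidative phosphorylation genes rose with axis 1 by small amounts that depended on 1 library, on batch 5209 and on covariates. Cytosolic ribosomal protein genes passed on both axes jointly for 19 of 22 and 19 when adjusted over the list alone, and 18 rose with axis 1 (22 when adjusted over the list alone), with a median slope of 0.079. Nuclear oxidative phosphorylation genes passed for 22 of 22 and 22 over the list alone, and 19 rose with axis 1, with a median slope of 0.071. Cox5a had 0.089 (SE 0.017) and Rpl3 had 0.10 (SE 0.018). Without library 38 of batch 5209, which had 10698007 counts, a TMM factor of 0.453 and 60.7% of its counts in 50 genes, 6 ribosomal protein and 14 oxidative phosphorylation genes rose, and the median slopes were 0.039 and 0.049. Without all 3 libraries that stood apart, 4 and 10 rose, with median slopes of 0.032 and 0.046. Camera with the preset correlation gave an adjusted p of 0.00215 and 3.02e-04 on axis 1, and 0.940 for both with an estimated correlation (adjusted p). On axis 2, 13 oxidative phosphorylation genes were lower (camera adjusted p = 0.00161 preset and 0.940 with an estimated correlation), and 10 were without library 38. The median ribosomal slope on axis 1 was 0.20 in batch 5209 and -0.013 in 5728, and that of 5209 was 0.13 without library 38 and 0.11 without the 3 libraries. That of oxidative phosphorylation genes was 0.15 in 5209 and 0.023 in 5728, and without library 38 it was 0.10 and 0.021. Mitochondrially encoded genes passed for 8 of 9, and 8 over the list alone, with a median axis 1 slope of 0.062. On axis 1 3 were higher. Without library 38 the median slope was 0.045, and 0 passed as higher. With total count, TMM factor and nuclear noncoding RNA as covariates, 4 ribosomal protein, 13 oxidative phosphorylation and 5 mitochondrially encoded genes passed on both axes jointly. With glial covariates 3, 8 and 4 did, and the median axis 1 slopes were -0.012, -0.011 and 0.036. The Rpl3 axis 1 slope was 0.022 with glial covariates and 0.0041 without batch 5209.

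Several markers of astrocytes and most markers of oligodendrocyte precursors were higher with axis 2 as single genes. Astrocyte markers passed for 7 of 12, or 8 when adjusted over the list alone, with 7 higher and 0 lower on axis 2, among them Fgfr3 at 0.17 (SE 0.021) and Slc1a2, a glutamate transporter gene, at 0.10 (SE 0.030). Oligodendrocyte precursor markers passed for 7 of 8 and 7 over the list alone, with 6 higher and 0 lower on axis 2, among them Neu4 at 0.16 (SE 0.017). With neighbouring tissue covariates 3 astrocyte and 5 precursor markers passed on both axes jointly. Camera with the preset correlation gave adjusted p of 0.00214 for astrocytes and 3.02e-04 for precursors on axis 2, and adjusted p = 0.940 and 0.198 with an estimated correlation. No list passed camera on either axis with an estimated correlation, at 64 tests of lists. Oligodendrocyte markers passed for 8 of 12, or 9 over the list alone, with 5 higher on axis 2, and 8 without library 38 of batch 5209. On axis 1 5 of them were lower and 1 higher. Ermn fell with axis 1, with a slope of -0.24 (SE 0.034). Across libraries, with each batch centred, the mean of the precursor list correlated with axis 2 at r = 0.393 (rho = 0.325, permutation p = 1e-05, adjusted p = 2.44e-04). That of the astrocyte list did at r = 0.301 (rho = 0.258, permutation p = 5.90e-04, adjusted p = 0.00499 over 220 relations). Without the 2 farthest libraries these r were 0.345 and 0.243. Within 3518, 5209 and 5728, r was 0.270, 0.444 and 0.371 for precursors and 0.0421, 0.368 and 0.314 for astrocytes. Both passed in 5209 and neither in 3518. In 5728 the precursors passed by r (adjusted p = 0.0314) but not by rho (0.284, adjusted p = 0.139), and the astrocytes did not pass (adjusted p = 0.0814, rho = 0.184). Without the 2 farthest libraries of 5728, r was 0.221 for precursors and 0.103 for astrocytes. In batch 3518 the astrocyte list correlated with axis 1, at r = -0.873 (rho = -0.947, permutation p = 2.00e-05, adjusted p = 4.40e-04, n = 16). Microglial markers had r = -0.762 (rho = -0.791, permutation p = 5.80e-04, adjusted p = 0.00499 for r and 0.00521 for rho) there. Without the 2 farthest libraries of 3518, r was -0.867 for astrocytes and -0.666 for microglia. In 5209 the microglial list had r = 0.377 (rho = 0.243, permutation p = 0.00613, adjusted p = 0.0346 for r and 0.265 for rho), and r was 0.196 without the 2 farthest libraries. Axis 2 itself favoured 2 components in 5209, of 33 and 18 libraries, with a Bayesian information criterion higher by 3.63 than for 1, and 1 component in 5728 and 3518. Within the lower and higher component r was 0.471 and 0.627 for precursors (adjusted p = 0.0735 and 0.0735 over 120 relations within components) and 0.316 and 0.0819 for astrocytes. No call with axis 2 in 5209 was kept within a component. For precursors r was not smaller there than the 0.444 of the whole batch. Whether that relation rested on the difference between components was therefore not settled. With glial covariates the Slc1a2 axis 2 slope was -0.0056 (adjusted p = 0.404 for both axes), but it is one of the genes averaged in those covariates.

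Signs of RNA and library quality moved with axis 1 as well. The mean of nuclear-retained noncoding RNAs, a list added after values were seen, correlated with axis 1 at r = -0.278 (rho = -0.250, permutation p = 0.00246, adjusted p = 0.0187 for r and 0.0375 for rho) with each batch centred. Within 5209 it had r = -0.507 (rho = -0.447, permutation p = 1.10e-04, adjusted p = 0.00127 for r and 0.0107 for rho), and within 5728 r = -0.297, which did not pass (adjusted p = 0.101). Within 3518 the sign was opposite, with r = 0.700 (rho = 0.638, permutation p = 0.00269, adjusted p = 0.0191 for r and 0.0523 for rho). Without the 2 farthest libraries r was -0.265 with each batch centred, -0.508 in 5209 and 0.721 in 3518. With axis 2 the list had r = -0.238 (rho = -0.233, permutation p = 0.00569, adjusted p = 0.0338 for r and 0.0475 for rho), and it passed in no single batch, at 0.266, -0.341 and -0.291 in 3518, 5209 and 5728. The log2 TMM factor had r = -0.383 (rho = -0.410, permutation p = 4.10e-04, adjusted p = 0.00410 for r and 0.0282 for rho) with axis 1 in 5209 and r = 0.657 (rho = 0.691, permutation p = 0.00540, adjusted p = 0.0330 for r and 0.0302 for rho) in 3518. It did not pass in 5728 (r = 0.0638) or with each batch centred (r = -0.218, adjusted p = 0.0516). Without the 2 farthest libraries its r was -0.258 in 5209 and 0.679 in 3518. With axis 2 and each batch centred it passed by rho (-0.263, adjusted p = 0.0282) but not by r (-0.0139, adjusted p = 0.965). The 4 libraries of 3518 with high Arntl had the lowest axis 1 values of that batch. Their TMM factors were 0.959 to 1.006, against 1.016 to 1.054 in the other 12. Whether the relations of 3518 with axis 1 hold without these 4 was not tested. The mitochondrial share of counts had r = 0.435 (rho = 0.267, permutation p = 2.50e-04, adjusted p = 0.00262 for r and 0.205 for rho) with axis 1 in 5209, and r was 0.216 without the 2 farthest libraries. The share in the 50 most abundant genes had r = -0.640 (rho = -0.497, permutation p = 0.00784, adjusted p = 0.0425 for r and 0.198 for rho) in 3518, and -0.387 without the 2 farthest. Axis 1 favoured 2 components in 5209, of 29 and 22 libraries, and in 5728, of 36 and 20, with a Bayesian information criterion higher by 13.4 and 13.1 than for 1, but 1 component in 3518. Of the genes that define the axes, Per2 favoured 2 components in 5209 (by 10.7 over 1). For Nr1d1 in 3518 and 5209, 2 components exceeded 1 by 5.62 and 5.50, but 3 components had the highest value. Per2 in 3518 also had its highest value with 3 components. Relations with axis 1 over a whole batch can therefore rest on the difference between components. Within the lower and higher component of 5209, r with axis 1 was -0.251 and 0.0376 for noncoding RNAs, -0.250 and 0.537 for microglia, -0.422 and -0.622 for the TMM factor, and 0.204 and 0.741 for the mitochondrial share. Of these the TMM factor (adjusted p = 0.0180) and the mitochondrial share (adjusted p = 0.00840) passed by r in the higher component, at -0.370 and 0.450 without its 2 farthest libraries. Of the 120 relations within components 5 passed by r and 0 by rho. The narrower range of an axis and the fewer libraries within a component can by themselves weaken a relation. Oligodendrocyte markers passed in the lower component of 5209 (r = -0.590, adjusted permutation p = 0.0211). The share in the 50 most abundant genes passed in its higher component (r = 0.628, adjusted permutation p = 0.00840). Paraventricular and supraoptic markers passed in the higher component of 5728 (r = 0.694, adjusted permutation p = 0.0211). There the mitochondrial share ran opposite to 5209 and did not pass (r = -0.639, adjusted permutation p = 0.050). Whether these relations differ between batches was not tested.

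Endothelial markers passed for 8 of 11 and 8 when adjusted over the list alone. On axis 2 4 were higher and 1 lower, the lower one being Cldn5, a tight junction gene, at -0.23 (SE 0.033). On axis 1 1 was higher and 5 were lower. Without the 3 libraries that stood apart, 3 were higher and 2 lower on axis 2, and 0 were higher and 3 lower on axis 1. Leptomeningeal and pericyte markers passed for 7 of 12 and 7 over the list alone. With glial covariates the median endothelial slope turned from -0.034 to 0.040 on axis 1 and from 0.050 to -0.092 on axis 2. The leptomeningeal and pericyte median turned from -0.11 to 0.098 on axis 1 and from 0.0095 to -0.15 on axis 2. In batch 3518 (n = 16) both lists correlated with axis 2 by rho, with r = -0.583 (rho = -0.697, permutation p = 0.0174, adjusted p = 0.0780 for r and 0.0294 for rho) for endothelial and r = -0.571 (rho = -0.671, permutation p = 0.0218, adjusted p = 0.0874 for r and 0.0375 for rho) for leptomeningeal and pericyte markers, and neither passed by r. These r were -0.682 and -0.715 without the 2 farthest libraries of 3518. With each batch centred r was -0.0436 and -0.0127, in 5209 0.0675 and 0.0410, and in 5728 -0.123 and 0.0336. Microglial markers passed for 4 of 12 and 4. Ependymal and tanycyte markers passed for 3 of 12, or 1 over the list alone, which was Vim. Choroid plexus markers passed for 3 of 8, or 2 over the list alone, and erythrocyte genes for 2 of 4, or 3. Markers of other hypothalamic neurons passed for 5 of 11 and 5 over the list alone, and 4 were lower on axis 2, among them Pmch at -0.88 (SE 0.24) and Slc17a6 at -0.081 (SE 0.031). The mean of that list had r = -0.272 (rho = -0.212, permutation p = 0.00255, adjusted p = 0.0187 for r and 0.0916 for rho) with axis 2 with each batch centred and r = -0.199 without the 2 farthest libraries. Within 3518, 5209 and 5728 r was 0.178, -0.379 and -0.211, of which 5209 passed, and -0.360 and 0.136 within the lower and higher axis 2 component of 5209, of which neither passed. With glial covariates the Pmch axis 2 slope was 0.16 (adjusted p = 0.734 for both axes), and 2 genes of the list passed. Pmch did not pass either with limma-voom (slope -0.45, adjusted p = 0.158), and the Slc17a6 axis 2 slope missed the threshold with any 1 batch left out (adjusted p from 0.0684 to 0.128). Paraventricular and supraoptic markers passed for 1 of 7, or 0 over the list alone, and forebrain markers for 2 of 7, or 1. With glial covariates 9 microglial, 1 choroid plexus, 0 erythrocyte and 1 forebrain genes passed, and erythrocyte genes passed for 0 with library quality covariates. The microglial genes are themselves averaged in the glial covariates, so their count there is not independent of them.

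The tissue content of the libraries varied. The mean of the SCN neuron list had a median of 4.89 log2 CPM and ranged from 4.29 to 5.68. With each batch centred it correlated with the oligodendrocyte list at r = 0.642 (rho = 0.624) and with markers of other hypothalamic neurons at r = -0.481 (rho = -0.437). Both had a permutation p of 1e-05 and an adjusted p of 2.44e-04 for r and 2.75e-04 for rho over the 220 relations. Without the 2 farthest libraries r was 0.627 and -0.434. Within batches the relation with oligodendrocytes was 0.629 in 5209, 0.731 in 5728 and 0.0122 in 3518, and that with other hypothalamic neurons was -0.566 in 5209, -0.456 in 5728 and 0.464 in 3518, so that neither held in 3518. Pmch, the gene of melanin-concentrating hormone, made by neurons of the lateral hypothalamus, had a median of 223 CPM (44.1 to 373) in batch 3518, 6.40 CPM (0.635 to 350) in 5209 and 1.58 CPM (0.539 to 22.9) in 5728. Hcrt, the gene of the orexin peptides of the same region, had medians of 17.3, 4.82 and 5.03 CPM. The mean of the other hypothalamic list had medians of 5.06, 4.09 and 4.27 log2 CPM in 3518, 5209 and 5728, and of 4.86, 4.37 and 4.63 without Pmch. Forebrain markers had 2.65, 2.18 and 2.13, and SCN neuron markers 4.51, 4.95 and 4.95.

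**Figure D3:**
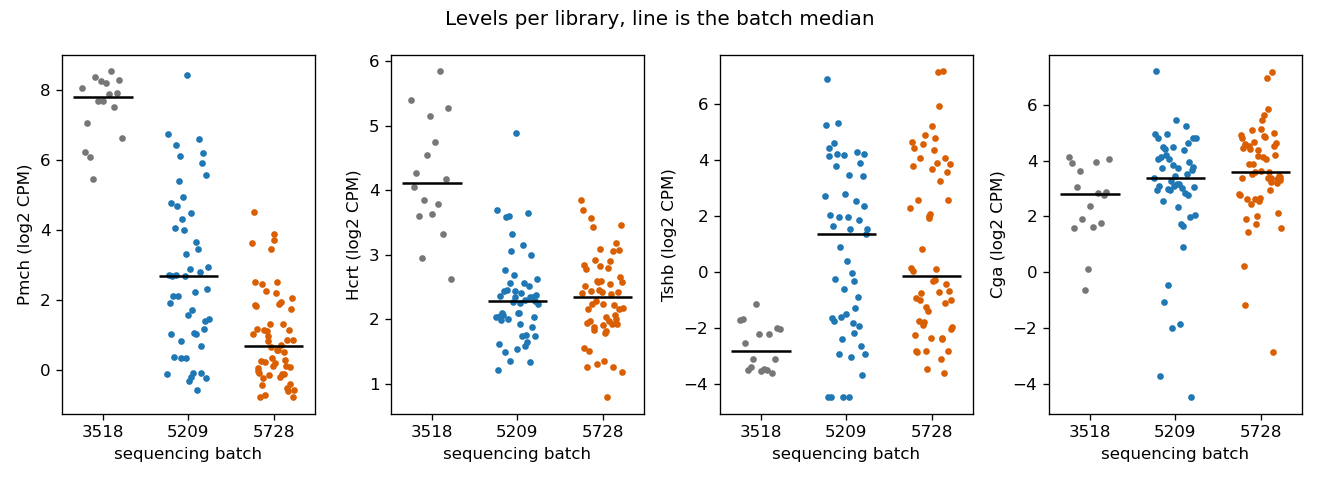
Each point is a library and each line a batch median, for Pmch, Hcrt, Tshb and Cga in log2 CPM by sequencing batch. The Pmch medians correspond to 223 CPM in 3518, 6.40 CPM in 5209 and 1.58 CPM in 5728.

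The last comparison was between sequencing batches 5209 and 5728, which both mix photoperiods and times. Bc1 (ENSMUSG00000115783.3), a small noncoding RNA of neurons named after its values were seen, had a median of 3.03 CPM in 5209 and 67.8 CPM in 5728, a log2 difference of 4.18 (SE 0.15). Of the leptomeningeal and pericyte list, Igf2 was higher in 5728 by a log2 difference of 1.21 (SE 0.12), Col1a1 by 1.05 (SE 0.12) and Slc6a13 by 1.03 (SE 0.11). Rgs5, a pericyte marker of the same list, did not pass, with a log2 difference of 0.076 (SE 0.054) (adjusted p = 0.210 in edgeR), and of the 12 genes 11 were higher and 0 lower (11 called when adjusted over the list alone), with a median of 0.79. Pmch was lower in 5728, with a log2 difference of -2.95 (SE 0.36), as was Crh, the corticotropin-releasing hormone gene, at -1.39 (SE 0.18). The list of other hypothalamic neurons, which holds Pmch, did not move as one. Of 11 measured genes of other hypothalamic neurons 6 were higher in 5728, among them Nr5a1 at 0.29 (SE 0.10) and Npy at 0.56 (SE 0.14), and 2 lower, Pmch and Slc17a6 (-0.23 (SE 0.049)), with 8 called when adjusted over the list alone and a median of 0.28. Of 7 genes on the paraventricular and supraoptic list 4 were lower and only Ghrh was higher, at 0.38 (SE 0.12). In that list 5 were called over the list alone, with a median of -0.15. Vip differed by -0.36 (SE 0.086) (adjusted p = 9.02e-05 in edgeR) and Avp by 0.22 (SE 0.088) (adjusted p = 0.0218 in edgeR). These genes were picked from the lists after their values were seen. Of 19412 genes, 13385 differed in edgeR's quasi-likelihood test, 6374 higher and 7011 lower in 5728, and 641 by over 2-fold. Other lists moved as well. Endothelial markers were higher in 5728 for 10 of 11 (median 0.31) and ribosomal protein genes for 21 of 22 (median 0.29), with 0 lower in either. Nuclear-retained noncoding RNAs were lower for 7 of 8 and higher for 0 (median -0.69). Mitochondrially encoded genes were lower for 6 of 9 and higher for 1 (median -0.38). The batches differ in their shares of LONG and SHORT samples and of projected zeitgeber times. The labels also give each sample a collection cycle, 1 or 2. Most 5209 samples came from cycle 1 and most 5728 samples from cycle 2. Batch, photoperiod, time and collection cycle are therefore not separated here.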

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

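Chosen only after the result was seen were the test of slopes between batches, the added covariates for tissue content, glial content and library quality, the tests on Pmch, and the correlations of heat shock genes with Cirbp and Rbm3. All these patterns were noticed in the data first. The slopes on the clock gene axes differed between batches 5209 and 5728 for 1138 of 18192 genes, by an interaction term in edgeR. In 100 random splits of the libraries, tested with limma-trend, the real split gave 1280 genes and the highest of the others gave 2. Only 1 of the 100, the real one, reached that count, so a random division of exchangeable libraries does not give it. By the labels the samples come in blocks that share time, photoperiod and RNA extraction batch, which the splits broke. Chance differences between such blocks were not tested. The axis 1 slope was 0.10 in 5209 and -0.065 in 5728 for Gabrg1, a GABA receptor subunit gene, -0.094 and -0.22 for Npas2, and -0.055 and 0.36 for Avp, genes named after their values were seen. Of the 22 ribosomal protein genes 19 differed, and 6 did without library 38 of batch 5209. The batches differ in their photoperiods, times, collection cycles and depth, and no explanation other than a random division of libraries was tested.

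The first pattern weighed is the 10719 genes that varied with the axes. Shuffling the axes among libraries of a batch gave at most 2 genes in limma-trend against 10848 for the real axes. The real axes were 1 of 100 arrangements, so a random arrangement of exchangeable libraries does not give that count. The shuffles broke the blocks of samples that share time, photoperiod and RNA extraction batch, so chance between blocks was not tested. With total count, TMM factor and the nuclear noncoding RNA score as covariates 10460 genes passed, and with the glial covariates 9933 did. Within batches the former explained 10.2% and 7.43% of the variance of axes 1 and 2, and the latter 7.47% and 16.1%. The counts argue against either measure, as scored here, as the whole cause. They say little about quality or glial content that these scores miss. Of 22 ribosomal protein genes 4 and 3 passed then, against 19 without covariates. With oligodendrocyte and SCN neuron scores 11190 passed, but these scores explained 0.178% and 1.36% of the variance of axes 1 and 2 within batches, so that count decides nothing and these tissue shares stay open. RNA extraction batch, which the labels tie to some times and photoperiods and which could not be matched to files, stays open and untested, as do time of day and photoperiod.

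The second pattern is the opposite slopes of the heat shock genes and Cirbp on axis 1, whose mean heat shock score correlated with Cirbp at r = -0.798 (rho = -0.824, both permutation p 1e-05, adjusted p = 2.50e-05 for r over 20 relations, n = 123) with each batch centred, at -0.858, -0.839 and -0.739 within 3518, 5209 and 5728, and at -0.810 without the 2 farthest libraries. With Rbm3, the other gene of the list that rose with axis 1, r was -0.316 (rho = -0.394, permutation p = 3.70e-04, adjusted p = 6.73e-04), and it passed within 5209 (-0.518) but not within 3518 (-0.278, permutation p = 0.296) or 5728 (-0.116, permutation p = 0.397). Handling that acutely activates neurons would raise immediate early genes together with heat shock genes, but those scores correlated at -0.0178 (rho = 0.00367, permutation p = 0.844). The median axis 1 slope of the 16 heat shock genes was -0.171, and with library quality and glial covariates it was -0.189 and -0.224. These covariates explained 10.2% and 7.47% of the variance of axis 1 within batches. The slopes argue against both, as scored here, as the whole cause. With oligodendrocyte and SCN neuron scores the slope was -0.178, which decides nothing, since these hardly track the axes over all libraries. Oligodendrocyte markers did correlate with axis 1 in the lower axis 1 component of 5209 (r = -0.590, rho = -0.566, adjusted permutation p = 0.0211 for r and 0.0860 for rho). Oligodendrocyte and SCN neuron content, handling that does not act through immediate early genes, RNA extraction batch, time of day and photoperiod stay open.

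The third pattern is the high Pmch of batch 3518, where markers of other hypothalamic neurons without Pmch had a median of 4.86 log2 CPM against 4.37 in 5209 and 4.63 in 5728, forebrain markers 2.65 against 2.18 and 2.13, and SCN neuron markers 4.51 against 4.95 and 4.95, differences that were not tested. Tissue from beside the SCN may contribute, since Pmch and Hcrt correlated at r = 0.524 (rho = 0.446, both permutation p 1e-05, adjusted p = 2.50e-05 for r, n = 123) with each batch centred, at 0.688, 0.626 and 0.413 within 3518, 5209 and 5728, and at 0.451 without the 2 farthest libraries, but this bears on variation within batches. The SHORT photoperiod as the whole cause is argued against by batch 5728, because 0 of the 56 libraries of 5728 reached the lowest level of 3518, although 26 samples of that batch are labelled SHORT. In 5209, 8 of the 51 libraries reached that level, with 16 samples labelled SHORT. All 8 had library numbers from 4 to 20, although the batch is numbered from 1 to 66. A part for photoperiod stays open there, but it could not be told apart from whatever the library numbers follow. A library batch effect and a difference in dissection cannot be told apart, because no file could be matched to the dissections or RNA extraction batches within 3518, whose median lay 7.10 log2 units above that of 5728.

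For the 13385 genes that differed between batches 5209 and 5728, limma-trend gave 13015 genes for the real split. The others of 100 splits gave at most 1, so a random division of exchangeable libraries does not give that count. These splits broke the same blocks of samples, so chance between blocks was not tested.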

How the results depend on the processing

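Chosen after seeing the data were the covariates, the fit with no batch term and the left-out libraries, limma-voom and axis covariates for the batch comparison, and every alternative for the slopes between batches. No paired analysis was possible because no file could be matched to a replicate number. The count of genes varying with the clock gene axes across libraries was 10719 and ran from 7224 without batch 5728 to 12154 with no batch term, except for 6959 with axis 1 alone, which tests 1 axis instead of both. For clock gene correlations across libraries 11 or 12 of 16 passed in each alternative except batch 3518 alone, with 6 in its 16 libraries. The sequencing batch differences ran from 13306 genes with limma-voom to 15718 with no filter. The axis slopes 5209 against 5728 differed for 910 genes without library 38 of 5209 to 1360 with RLE. The 16 heat shock genes had negative axis 1 slopes in each of the alternatives run, with medians from -0.224 to -0.138. Among single genes and relations, 4 called values missed the threshold with the same direction with RLE, 59 without batch 5209, 68 without batch 5728, 44 with glial and 39 with library quality covariates. These called values changed direction, whether or not they passed then. The correlation of Arntl with Nr1d1 was 0.197 and the correlation of Arntl with Bhlhe41 0.127 in 3518 alone, and the correlation of Arntl with Per3 was 0.0947 and the correlation of Arntl with Avp 0.0115 in 5209 alone. Without batch 5209 the Atp5a1 axis 1 slope was -0.00674, the Atp5b axis 1 slope -3.34e-05, the Bcan axis 1 slope -0.00183, the Clic6 axis 1 slope -0.0127, the Cox4i1 axis 1 slope -0.0205 and the Hba-a1 axis 1 slope -0.183. The Ndufa2 axis 1 slope was -0.0334, the Rpl13 axis 1 slope -0.00542, the Rpl18 axis 1 slope -0.0121, the Rpl27 axis 1 slope -0.0486, the Rpl30 axis 1 slope -0.0414 and the Rpl32 axis 1 slope -0.0237. The Rpl8 axis 1 slope was -0.0298, the Rplp0 axis 1 slope -0.0308, the Rps14 axis 1 slope -0.0969, the Rps18 axis 1 slope -0.0334, the Rps19 axis 1 slope -0.0524 and the Rps3 axis 1 slope -0.0660. The Rps6 axis 1 slope was -0.0446, the Sdha axis 1 slope -0.0108, the Sparc axis 1 slope -0.0461, the Ttr axis 2 slope -0.730, the Uqcrh axis 2 slope 0.00680 and the mt-Co3 axis 2 slope -0.141. The mt-Cytb axis 1 slope was -0.0434, the mt-Nd1 axis 1 slope -0.0355 and the mt-Nd4 axis 1 slope -0.0558. With glial covariates the Abcb1a axis 2 slope was -0.0916, the Adcy9 axis 2 slope -0.0230, the Aqp4 axis 2 slope -0.0639, the Atp5j2 axis 2 slope 0.00202, the Bmp4 axis 2 slope -0.0366 and the Cacna1c axis 1 slope 0.0248. The Cdh5 axis 1 slope was 0.0504, the Cldn11 axis 2 slope -0.00671, the Col1a2 axis 2 slope -0.136, the Cox6c axis 2 slope 0.0172, the Cox7a2 axis 2 slope 0.0184 and the Cox7b axis 2 slope 0.0209. The Csnk1e axis 2 slope was 0.00484, the Cspg4 axis 2 slope -0.0764, the Dcn axis 1 slope 0.0260, the Flt1 axis 1 slope 0.0122, the Gal axis 2 slope 0.00431 and the Gfap axis 2 slope -0.00385. The Hba-a1 axis 1 slope was -0.0859, the Itm2a axis 2 slope -0.0518, the Kcna1 axis 2 slope -0.0164, the Kdr axis 1 slope 0.0205, the Lum axis 2 slope -0.0126 and the Mag axis 2 slope -0.0607. The Ndufa2 axis 1 slope was -0.0329, the Ndufa4 axis 2 slope 0.00976, the Ndufb3 axis 2 slope 0.0199, the Ndufb9 axis 2 slope 2.76e-04, the Nr4a3 axis 2 slope -0.0398 and the Pdgfra axis 2 slope -0.0605. The Pmch axis 2 slope was 0.161, the Rarres2 axis 1 slope -0.00693, the Rpl18 axis 1 slope -0.00619, the Rpl19 axis 2 slope 0.0383, the Rpl27 axis 1 slope -0.0190 and the Rpl30 axis 1 slope -0.0166. The Rpl32 axis 1 slope was -0.0300, the Rpl8 axis 1 slope -0.00350, the Rplp0 axis 1 slope -0.00146, the Rps14 axis 1 slope -0.0355, the Rps18 axis 1 slope -0.0261 and the Rps19 axis 1 slope -0.0140. The Rps3 axis 1 slope was -0.0342, the Rps6 axis 1 slope -0.0101, the Slc12a2 axis 2 slope -0.0669, the Slc1a2 axis 2 slope -0.00555, the Slc6a11 axis 2 slope -0.0234 and the Slc6a13 axis 1 slope 0.0767. The Slco1a4 axis 2 slope was -0.0326, the Timp3 axis 2 slope -0.00516, the Tnr axis 1 slope 0.0201, the Uqcrc2 axis 1 slope -0.0110, the Uqcrh axis 2 slope 0.0234 and the Wnk1 axis 2 slope -0.0568. The Zfhx3 axis 2 slope was -0.0472 and the mt-Nd5 axis 2 slope -0.00274. With library quality covariates the Hba-a1 axis 1 slope was -0.0342. With limma-voom the Npas4 axis 1 slope was -0.0250, the Ttr axis 2 slope -0.127 and the mt-Co3 axis 2 slope -0.0546. With no batch term the Ier5 axis 2 slope was 2.42e-04, the Slc6a13 axis 1 slope 0.0126, the mt-Co1 axis 2 slope -0.0333 and the mt-Nd5 axis 2 slope -0.105. Without batch 5728 the Alas2 axis 2 slope was -0.0969. Without the libraries apart the Hba-a1 axis 1 slope was -0.0242. The glial covariates average astrocyte, precursor and microglial markers, so their own members' slopes there are not independent of them. The cause was not tested. Alternatives for LONG against SHORT, rhythms, phases and lists between photoperiods were not run. Depth limits genes near 1 CPM, such as Prok2, in the shallowest library of 10698007 counts.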

Other observations

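The pituitary, olfactory and nuclear noncoding RNA lists and the check for components below were chosen after values were seen. Tshb, which encodes the thyrotropin beta subunit and is made in the pituitary and its pars tuberalis, had a median of 0.0993 CPM (0.0366 to 0.412) in batch 3518, 2.51 CPM (0 to 120) in 5209 and 0.877 CPM (0.0377 to 144) in 5728. Cga, which encodes the subunit it pairs with, had 6.89 CPM (0.598 to 17.5), 10.3 CPM (0 to 146) and 12.0 CPM (0.0943 to 145). Tshb levels favoured 2 components in each batch, with a Bayesian information criterion higher by 2.25 in 3518, 1.72 in 5209 and 14.7 in 5728 than for 1, so its correlation with Cga is given within components (6 relations). In 5728 r was 0.593 in the lower 32 libraries (rho = 0.582, adjusted permutation p = 3.60e-04) and 0.870 in the higher 24 (rho = 0.826, adjusted permutation p = 3.00e-05). In 5209 it was 0.494 in the lower 24 (rho = 0.473, adjusted permutation p = 0.0206) and 0.784 in the higher 27 (rho = 0.733, adjusted permutation p = 3.00e-05). These 4 r were 0.604, 0.759, 0.317 and 0.762 without the 2 farthest libraries. In 3518 neither component of 8 passed by permutation, with r of -0.0616 and -0.159. Those 2 values turned to 0.432 and 0.686 without the 2 farthest libraries. Tshb did not pass on the axes (adjusted p = 0.240 in edgeR). Of the pituitary list 1 of 6 measured genes passed on the axes, and 0 when adjusted over the list alone. 3 of its 8 genes stand in another list. The mean of the list had r = -0.390 (rho = -0.327, permutation p = 0.00419, adjusted p = 0.0279 for r and 0.0887 for rho) with axis 1 in 5209, and r = -0.293 without the 2 farthest libraries. With each batch centred r was -0.128 (adjusted p = 0.373), and it was -0.283 in 3518 and 0.176 in 5728. Within the lower and higher axis 1 component of 5209 it was 0.384 and -0.234 (adjusted p = 0.291 and 0.543), so the relation in 5209 was not called within components. Their narrower range of axis 1 and smaller number of libraries can by themselves weaken r.

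Transcripts of other tissues were high in some libraries. Omp, a marker of olfactory sensory neurons, had a median of 4.41 CPM and reached 330 CPM in 5209, and Cyp2g1, expressed in olfactory mucosa, had a median of 0.0385 CPM and reached 138 CPM. The olfactory list did not pass on the axes, with adjusted p in edgeR from 0.171 for Cyp2a5 to 0.905 for S100a5 over its 8 genes. Ttr, an abundant transcript of the choroid plexus, had a median of 2.25 CPM and reached 667 CPM, and Slc17a7, of forebrain excitatory neurons, reached 76.4 CPM in 3518. Meg3, a nuclear noncoding RNA, ranged from 45.2 to 1539 CPM. Of the nuclear noncoding RNA list 6 of 8 passed, and 6 when adjusted over the list alone. On axis 1 5 were lower, with a median slope of -0.30 over the list. Without library 38 of batch 5209, 0 passed as lower and the median slope was -0.25, and it was -0.26 without the 3 libraries that stood apart.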
